A study of Mus musculus with 6 samples.

How the data were processed

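Total RNA from liver was extracted with Trizol, and 250 ng was labelled with a 3' IVT kit and hybridised to Affymetrix MG-430 PM strip arrays, per the labels. The 6 arrays fall into 3 wild-type and 3 Nrg4 knockout arrays, named by the genotype and replicate number in the labels, which call the replicates biological and describe each as a pool. The submitters' processing notes name affy, RMA and limma; their versions, and any genome build, are not given in the sources used here. The deposited table holds log2 RMA values (robust multi-array average, which subtracts background, normalizes by quantiles and summarises probes), so array medians are close to each other by construction and a shift of most genes in one direction would be reduced.

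Of 45141 probe sets, 104 were controls, 28898 had 1 gene symbol, 551 had several and 15588 others had none here. Probe sets with several symbols or none entered no gene-level test. Of those with 1 symbol, 28689 matched a RefSeq gene of assembly GRCm38.p6 by gene number, and this table was used only for names and for which genes neighbour each other. List members were matched by symbol, and by synonym only where the symbol was not the current symbol of another gene. A gene was represented by its probe set with the highest mean over the 6 arrays. Genes under the 40th percentile of probe set means (log2 2.66) were left out as dim, which left 12466 of 17097 genes. This limit is a percentile of probe set means and was not set from background signal. Control probe sets for nonspecific signal had array medians of 1.65 to 1.76, and their highest values were 5.29 to 5.84. Passing the limit therefore does not by itself show signal over background.

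The genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided, default prior) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over all 35 lists, with an estimated correlation and fry as further tests. The 6 primary lists are fatty acid synthesis, cholesterol synthesis and uptake, triglyceride synthesis and lipid droplets, fatty acid oxidation and ketogenesis, gluconeogenesis and glucose handling, and ErbB receptors, ligands and targets. The 29 secondary lists cover other liver pathways, cell markers, sex, time of day and handling. Calls near Nrg4 were counted within 10 Mb with Fisher's exact test. The design, these tests, the list members, the rule for named genes and all alternatives but those said to be added were fixed before the data were examined. The rule for synonyms was set after first results were seen, and it moved the fry adjusted p of the fatty acid synthesis list from under to over 0.05. Some tests of explanations in the closing section were also chosen later and are named there.

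The genes named are every Nrg4 probe set and the ErbB receptors; in each direction 12 genes, first those past the threshold with no overlap between genotypes by size and then those with the smallest unadjusted p; the 4 members with the smallest p of each primary list and 3 of each secondary list that passed; and genes called within 10 Mb of Nrg4. The other genes and unnamed probe sets spoken of in the text were chosen after their values were seen.

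The alternatives were quantile normalization again, centring on array medians, no filter or a filter at the 60th percentile, a variance trend, a robust prior, array weights, the mean of all probe sets of a gene, leaving out each array, the replicate number as a block, every probe set on its own, adjusted p under 0.10, a minimum of 1.5-fold, treat against 1.2-fold, and windows of 5 and 20 Mb. A 5' to 3' covariate and a run without genes within 20 Mb of Nrg4 were added after seeing the data.

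The gene test was checked on simulated data for the 12466 genes, in 10 draws with 200 changed genes each. It found 61.6% of genes changed by 0.5 on the log2 scale and 98.6% of those changed by 1, and 5.71% of its calls were false. A fatty acid synthesis list shifted by 0.3 was found in 10 of 10 draws, and 2 of 340 tests of other lists were called. Genes were drawn as independent, so these shares do not cover correlated genes. Each draw held 200 changed genes, and more true changes make the adjusted threshold easier to reach. Only 5 genes passed in the data, so the shares found can be too high for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.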

Results

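Liver gene expression was measured in wild-type mice and in mice lacking Nrg4, which encodes neuregulin 4, a secreted ligand of the ErbB receptor family that is enriched in brown fat. The strain is labelled only as C57BL/6. All mice ate a high-fat diet for 8 weeks from 3 months of age and were random-fed at harvest. Each genotype was represented by 3 arrays, and each array by an independent pool of liver RNA. The number of mice in a pool is not given in the sources used here, so the p-values describe the spread between pools. Each array gave 45141 log2 values between 1.03 and 12.53, with array medians of 2.98 to 3.04. The number of arrays limits the precision, and an exact permutation test of 3 against 3 arrays cannot give a p below 0.1. The signal of the Y-linked gene Eif2s3y lay between 7.16 and 7.46 in the 6 arrays.

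The first question was whether the arrays carried the genotype on their labels. Nrg4 was 4.94, 4.79 and 4.77 in the wild-type arrays and 2.56, 2.43 and 2.64 in the knockout arrays on the log2 scale. It fell by 2.30 (SE 0.10, n = 3 arrays per genotype, limma adjusted p = 4.76e-05). The gene was 4.91-fold lower as measured. The knockout values lay under the limit for dim probe sets, and the wild-type mean was 4.51-fold over that limit. The limit is a percentile of probe set means and not a floor of detection, so it sets no bound on the fall. A single probe set represented Nrg4, and whether it lies in the deleted part of the gene is not stated in the sources used here. The receptors of this ligand family did not pass the test. Egfr had a log2 change of -0.13 and Erbb3 of -0.08, with limma adjusted p-values of 0.832 and 0.807. Erbb2 stood at 0.24 with a limma adjusted p of 0.597. Erbb4 was below the limit for dim probe sets, at 1.71 ± 0.08 in wild type and 1.98 ± 0.19 in the knockout (SD, n = 3). The list of ErbB receptors, ligands and targets had 7 members with a higher and 8 with a lower value of 15 tested, and a median log2 change of -0.01 (camera adjusted p = 0.673). Erbb4, Nrg1, Btc, Ereg, Egf and Etv4 were left out of the list as dim, and Areg had no probe set. The list thus says little about the ligands. Its members with the smallest p, Etv5 at 0.42, Stat3 at 0.20, Erbb2 and Dusp6 at -0.28, did not pass over all genes.

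The main comparison asked which liver genes differed between the genotypes. Besides Nrg4, 4 genes passed. Apoa4, an apolipoprotein of triglyceride-rich lipoproteins, was 3.44-fold higher in the knockout, rising from 9.09 ± 0.30 to 10.88 ± 0.19 (SD, n = 3; limma adjusted p = 0.0141). Tex12, a component of the synaptonemal complex, was 1.81-fold higher (log2 change 0.85, SE 0.09, limma adjusted p = 0.0275). Its wild-type mean of 2.97 lay close to the limit for dim probe sets, 2.66. Dixdc1, a DIX-domain protein of Wnt signalling, was 2.41-fold lower (log2 change -1.27, SE 0.15, limma adjusted p = 0.041). Glyctk, glycerate kinase, was 1.82-fold lower (log2 change -0.87, SE 0.09, limma adjusted p = 0.0275). In each of these genes the values of the knockout arrays and the wild-type arrays did not overlap. The main probe set of Dixdc1 carried its change alone, since another probe set of the gene above the limit for dim signal had a log2 change of 0.07 (SE 0.10). In all, 5 of 12466 genes passed at adjusted p under 0.05, 2 higher and 3 lower, and 30 passed under 0.10, 23 higher and 7 lower. The count was 17 without knockout replicate 1 and between 1 and 2 without any other array. Nrg4 alone passed in every one of these runs. With genes within 20 Mb of Nrg4 left out, an alternative chosen after seeing the data, 0 of 12202 genes passed limma's test. The lowest adjusted p was 0.107, and 1138 genes had an unadjusted p under 0.05. Glyctk stayed in that run with its log2 change unaltered, since leaving out other genes alters only the test and its adjustment.

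**Figure D1:**
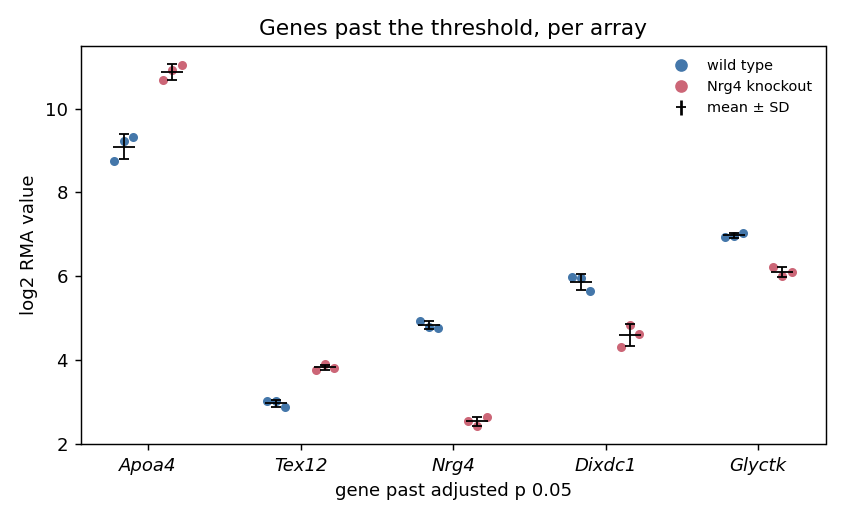
The 5 genes past the adjusted p threshold are on the horizontal axis and the log2 RMA value is on the vertical axis. Points are single arrays, and black bars give the mean ± SD of 3 arrays per genotype; Apoa4 and Tex12 lie higher in the knockout, and Nrg4, Dixdc1 and Glyctk lower.

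The genes next in order of unadjusted p did not pass at adjusted p under 0.05. On the higher side these were Cd36, the fatty acid translocase, with a log2 change of 0.74, Col14a1 at 1.00, Bckdhb at 0.72, Zbtb16 at 1.18, Gzmb at 0.61, Thrsp at 1.05, Cdca4 at 0.58, Lyve1 at 1.29, Emp1 at 1.23 and Lgals1 at 1.06. Their limma adjusted p-values lay between 0.0597 and 0.0743. The wild-type values of Gzmb and Emp1, with means of 2.51 and 2.28, lay under the limit for dim probe sets. On the lower side were Abhd14a at -0.65, Dapk2 at -0.82, Bco2 at -1.08, Apob at -1.16, Trappc4 at -0.46, Acot1 at -0.67, Esrrg at -0.72, Nnmt at -0.99 and C1rb at -0.47. All 3 probe sets of Cd36 gave log2 changes between 0.69 and 0.74, while another probe set above the dim limit stood at 0.06 for Zbtb16, -0.17 for Abhd14a and -0.10 for Trappc4. Among the genes tested, the values of the genotypes did not overlap in 15.6%, where chance gives 10% for 3 against 3 arrays. The median log2 change over all genes tested was 0.045. Of the 1190 genes at an unadjusted limma p under 0.05, 918 were higher in the knockout and 272 lower. Counts of higher list members below are thus not to be set against an even split.

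The title in the series text names hepatic lipogenesis, so fatty acid synthesis genes were examined as a list. They rose as a group: 15 of 18 members had a higher value in the knockout, with a median log2 change of 0.22 (camera adjusted p = 0.000524). The call was lost with an estimated correlation (adjusted p = 0.511) and in the directional fry test (adjusted p = 0.0603). Thrsp, a lipogenic regulator, was 2.07-fold higher and Me1, the malic enzyme that supplies NADPH, 1.61-fold higher. Me1 lay over 30 Mb from Nrg4 on the same chromosome, and Elovl5, another member (0.23), between 20 and 30 Mb. The list was not tested without these genes. Aacs, acetoacetyl-CoA synthetase, had a log2 change of 0.56 and Mid1ip1 of 0.46. No member passed over all genes, and 5 were higher adjusted over the list alone. The list means of the knockout arrays, 0.06, 0.22 and 0.13, lay above those of the wild-type arrays, -0.18, -0.11 and -0.12. The control probe sets of 18S ribosomal RNA separated the genotypes too: the 3' probe set read 6.89, 6.74 and 6.67 in the knockout and 7.45, 7.65 and 7.73 in wild type, the middle one 6.43, 6.59 and 5.74 against 7.92, 8.14 and 8.03, and the 5' one 6.06, 6.71 and 5.61 against 8.12, 8.80 and 8.69.

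Fatty acid oxidation and ketogenesis genes fell as a group by a small amount. Of 20 members, 14 had a lower value, and the median log2 change was -0.04 (camera adjusted p = 0.0091; fry adjusted p = 0.0247). With an estimated correlation the adjusted p = 0.511. Acot1, an acyl-CoA thioesterase, was 1.59-fold lower, Ehhadh had a log2 change of -0.21 and Fgf21, a fasting-induced hormone, of -0.51. The probe sets of Ppara, a regulator of these genes, disagreed: the brightest had a log2 change of 0.34 and the others -0.35 and -0.13. None of these passed over all genes, and 1 member was lower adjusted over the list alone. Fatty acid uptake and PPAR gamma targets were higher by camera: 10 of 12 members had a higher value, with a median log2 change of 0.14 (camera adjusted p = 0.0138; fry adjusted p = 0.0351). With an estimated correlation the adjusted p = 0.511. Cd36 was 1.67-fold and Lpl, lipoprotein lipase, 1.84-fold higher, and these 2 were higher adjusted over the list alone; Slc27a1 stood at 0.29. Cd36, Lpl, Pparg and Fabp4 are also expressed by macrophages or endothelium, whose marker lists had medians of 0.29 and 0.28. The camera call of this list was lost without knockout replicate 1 (median 0.05), with array weights (median 0.098) and with the mean of all probe sets (median 0.13); over 17 refits the adjusted p lay between 0.00482 and 0.192.

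Cholesterol synthesis and uptake genes fell in the camera test, with a lower value in 17 of 18 members and a median log2 change of -0.10 (camera adjusted p = 0.00468). With an estimated correlation the adjusted p = 0.879, and fry gave an adjusted p of 0.86. The wild-type arrays spanned list means of -0.55, 0.07 and 0.73, wider than the knockout arrays at -0.06, -0.20 and 0.02. Without wild-type replicate 3 the median turned to 0.10 (camera adjusted p = 0.713). Sc5d, a sterol desaturase, had a log2 change of -0.65, Lss of -0.46, Tm7sf2 of -0.21 and Insig1 of -0.16. Sc5d passed adjusted over the list alone and none passed over all genes. The other probe sets of Sc5d above the dim limit stood at 0.14 and -0.29, and the gene lay between 10 and 20 Mb from Nrg4.

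Triglyceride synthesis and lipid droplet genes did not pass as a list (median log2 change 0.11, camera adjusted p = 0.43). Plin4, a lipid droplet coat protein, stood at 0.61 and G0s2, an inhibitor of adipose triglyceride lipase, at -0.42, and both passed adjusted over the list alone. Gpat3 stood at 0.31 and Cidea at 0.52, the latter with a mean over all arrays of 2.79, close to the limit for dim probe sets. Gluconeogenesis and glucose handling genes did not pass either (median 0.10, camera adjusted p = 0.777), with Pygl at 0.22, Khk at 0.20, Irs1 at -0.27 and Gys2 at 0.26.

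Of the lists of cell markers, those of macrophages, of endothelium and of stellate cells and matrix were higher in the knockout by camera. Macrophage and Kupffer cell markers had a higher value in 17 of 18 members, with a median log2 change of 0.29 (camera adjusted p = 0.00454; 0.864 with an estimated correlation). Adgre1, which encodes F4/80, was 1.56-fold higher, Mpeg1 had a log2 change of 0.45 and Cd5l of 0.35. Sinusoidal endothelial markers were higher in 10 of 12 members (median 0.28, camera adjusted p = 0.0091, and 0.864 with an estimated correlation). They were led by Lyve1 at 2.44-fold, with Ptprb at 0.49 and Cdh5 at 0.38. Another probe set of Ptprb above the dim limit stood at -0.23 (SE 0.16). Stellate cell and matrix genes were higher in 13 of 16 members (median 0.17, camera adjusted p = 0.0091; 0.659 with an estimated correlation), with Col3a1 1.75-fold higher, Vim at 0.47 and Dcn at 0.40. No member passed over all genes; adjusted over the list alone, 1, 2 and 3 members were higher in these lists. With fry the adjusted p-values were 0.455, 0.455 and 0.192. The macrophage list mean of knockout replicate 1, -0.18, lay among the wild-type arrays (-0.06, -0.28 and -0.12), while knockout replicates 2 and 3 stood at 0.27 and 0.37. Without knockout replicate 1 the matrix list missed the threshold (camera adjusted p = 0.103), and without wild-type replicate 3 the endothelial list did (median 0.14, camera adjusted p = 0.348). The mean 5' minus 3' signal of the Actb and Gapdh controls was -1.31 in knockout replicate 1, -0.70 and -0.65 in knockout replicates 2 and 3, and between -0.96 and -0.78 in wild type.

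**Figure D2:**
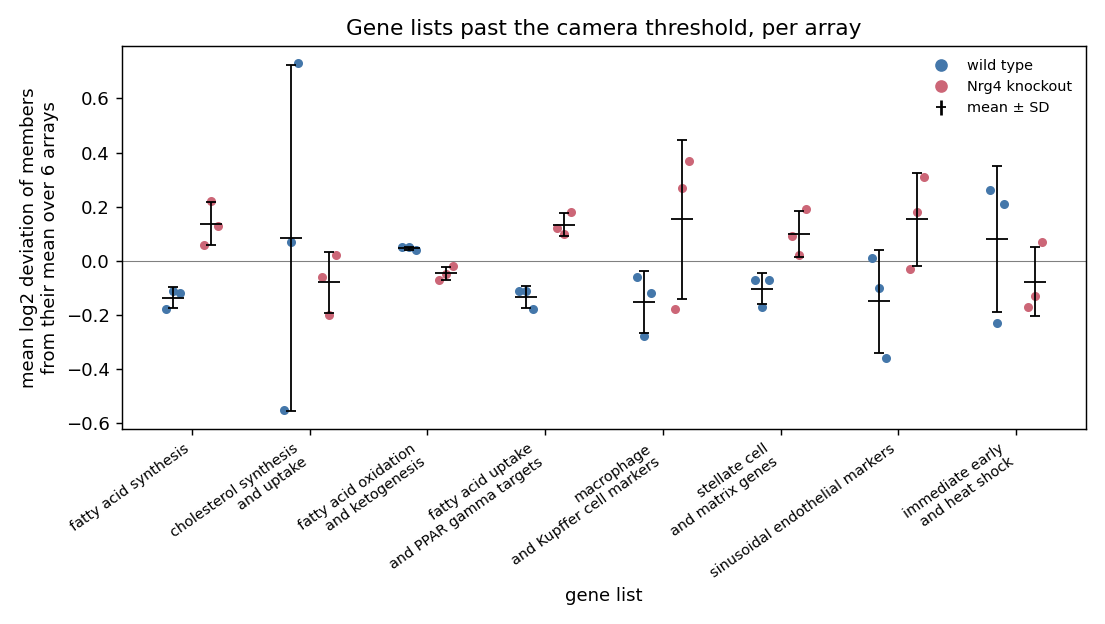
The 8 gene lists past the camera threshold are on the horizontal axis; the vertical axis is the mean log2 deviation of list members from their mean over the 6 arrays. Points are arrays and black bars the mean ± SD of 3 arrays; fatty acid synthesis separates the genotypes, while the wild-type arrays of the cholesterol list span -0.55 to 0.73.

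Immediate early and heat shock genes, which respond to handling, were lower in 12 of 14 members (median -0.19, camera adjusted p = 0.0138). With an estimated correlation the adjusted p = 0.659, and fry gave 0.738. Hsp90aa1 stood at -0.48, Hspa8 at -0.19 and Gadd45g at 0.36, none past the test. The call was lost without wild-type replicate 1 (median 0.001), without wild-type replicate 3 (median -0.05), without knockout replicate 1 (median -0.14) and with array weights (median -0.058, adjusted p = 0.283). None of the other lists passed, and no list passed with an estimated correlation. Their median log2 changes and camera adjusted p-values were 0.07 and 0.777 for lipoprotein assembly, -0.01 and 0.214 for bile acid synthesis and transport, 0.11 and 0.537 for drug metabolism, 0.03 and 0.777 for NRF2 targets and 0.03 and 0.777 for endoplasmic reticulum stress. Acute phase and inflammation gave -0.08 and 0.163, interferon response 0.09 and 0.673, cell cycle -0.03 and 0.697, circadian clock and output -0.04 and 0.43, and the growth hormone axis -0.06 and 0.777. Among cell markers, lymphocytes gave 0.09 and 0.701, neutrophils 0.06 and 0.777, cholangiocytes 0.20 and 0.43, hepatocytes -0.002 and 0.777, adipocytes -0.16 and 0.0696, pancreatic acinar cells 0.05 and 0.673, red blood cells -0.12 and 0.673 and skeletal muscle 0.004 and 0.777. Male-biased genes gave -0.01 and 0.0755, female-biased genes 0.62 and 0.133, the mitochondrial respiratory chain 0.06 and 0.777, pericentral genes -0.02 and 0.697, periportal genes 0.11 and 0.631, and lysosome and autophagy 0.12 and 0.515. Only 2 cholangiocyte, 3 red blood cell, 4 adipocyte, 4 female-biased, 5 acinar and 5 skeletal muscle members were tested. Lists this small say little when they do not pass. The median, mean, camera and fry directions were not all alike for the ErbB, NRF2, neutrophil, hepatocyte, acinar, red blood cell, muscle, cell cycle, growth hormone and pericentral lists.

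The last comparison asked whether genes that changed lay near Nrg4, since a knockout made in stem cells of another strain can keep flanking sequence of that strain. Apoa4, Tex12 and Dixdc1 lay within 10 Mb of Nrg4, and Glyctk lay on the same chromosome over 20 Mb away. Nrg4 aside, 3 of 143 genes tested within 10 Mb passed, against 1 of 12251 elsewhere (Fisher's exact test, two-sided, p = 5.97e-06). At adjusted p under 0.10 these were 5 of 143 and 24 of 12251 (Fisher's exact p = 1.81e-05). Of the genes named above that did not pass, Zbtb16, Bco2 and Nnmt also lay within 10 Mb. Dapk2, Trappc4, Sc5d and Hspa8 lay between 10 and 20 Mb, and Bckdhb and Elovl5 between 20 and 30 Mb. Me1 and Abhd14a lay over 30 Mb away on the same chromosome. At an unadjusted p under 0.01, 7.15% of the 685 genes on this chromosome changed, against 4.29% on the next highest chromosome. The count within 10 Mb was 0 without wild-type replicate 2, without knockout replicate 2 or without knockout replicate 3, where the total number of genes called, Nrg4 aside, was 0, 1 and 0. With the filter at the 60th percentile, where Tex12 was not tested, it was 1 of 2 genes called (Fisher's exact p = 0.0242).

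**Figure D3:**
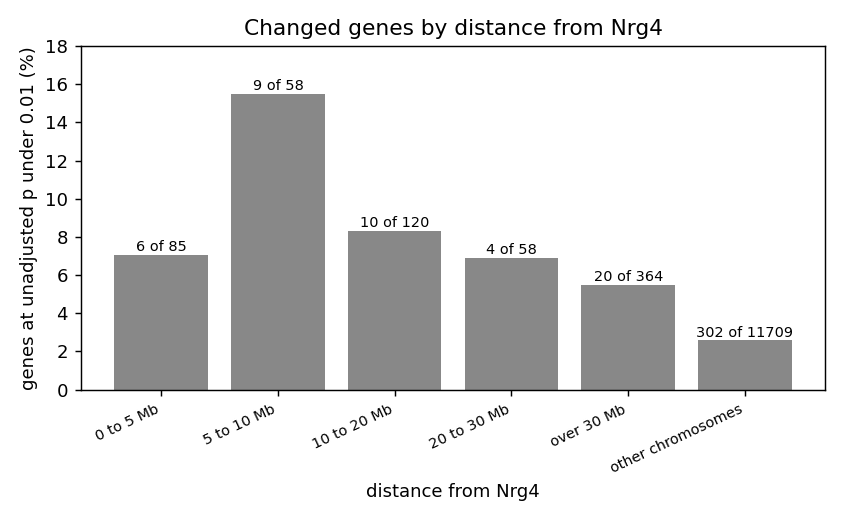
Bars give the percentage of tested genes at an unadjusted p under 0.01, by distance from Nrg4 on its chromosome and for all other chromosomes, with counts above the bars. The share was 7.06% within 5 Mb, 15.5% between 5 and 10 Mb, 8.33% between 10 and 20 Mb, 6.9% between 20 and 30 Mb, 5.49% beyond 30 Mb on the same chromosome and 2.58% on other chromosomes.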

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

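The use of Fisher's exact test against chance placement, the look at other probe sets of the higher genes near Nrg4 and of genes called by one of them, the minimum of 4 such probe sets, the 5' to 3' covariate and group means set against RNA degradation, the limit on dim markers and the test on brighter markers were chosen only after the result was seen. In the fit of every probe set, 14 probe sets without a gene name here passed, 3 higher and 11 lower in the knockout, of 8004 such probe sets tested. They stand outside the gene comparisons. The largest by fold were a 7.71-fold lower and a 4.26-fold higher probe set, with limma adjusted p-values of 0.00858 and 0.00929.

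Genes changed near Nrg4. Chance placement of the called genes is argued against by Fisher's exact p = 5.97e-06. Sequence differences under the probes, from flanking sequence of another strain, cannot be told apart. Of 143 genes within the window 7 were higher at an unadjusted p under 0.01 where chance gives 3.01 (one-sided exact binomial p = 0.0325). This was the bound set against the explanation, taking a mismatch to lower the knockout signal. That was wrong: the strain of the stem cells and of the probe sequences is not given in the sources used here, so a mismatch can go either way. The 7 genes had 1 other probe set above the dim limit, of Zbtb16, at 0.06 (SE 0.08). For the 8 lower genes, 1 of 3 other probe sets, 33.3%, was lower. These came from 2 genes: Dixdc1 at 0.07, and Dlat at -0.47 and at 0.28 (unadjusted p = 0.00831), opposite in direction. In the fit of every probe set, probe sets that do not represent their gene passed for Atm within 10 Mb (-1.21, adjusted p = 0.0198) and for Mpzl2 (1.53, adjusted p = 0.00158) and Mindy2 (-0.83, adjusted p = 0.0488) between 10 and 20 Mb, where the representing probe sets stood at 0.06, 0.20 and -0.11. Ibtk and Slc38a3, on the chromosome of Nrg4 but over 30 Mb away, showed this too (-0.66 against 0.02 and 1.09 against 0.32). So did Ppp2r5a, over 20 Mb away or on another chromosome (-1.21 against 0.06). Disagreeing probe sets are what a sequence difference would give, and differences between transcripts were not tested. Regulatory differences in flanking sequence and an effect of the missing ligand may both remain, and neither was tested.

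Macrophage, endothelial and matrix lists higher in the knockout. A linear trend with RNA degradation, as read by the 5' to 3' signal of Actb and Gapdh, is argued against as the whole cause. The knockout and wild-type means of that signal differed by 0.008, against an SD of 0.27 within genotypes. The test planned for this was undecided, since the knockout array with the lowest 5' to 3' signal had a mean over the 3 lists of -0.04, level with the highest wild-type array at -0.04, and the other knockout arrays stood at 0.16 and 0.29. With the signal as a covariate the medians were 0.28, 0.27 and 0.16 (camera adjusted p = 0.000755, 0.00639 and 0.0181). The number of genes called went from 5 to 12. The list calls are at the preset correlation. Without the covariate they are lost at an estimated correlation (camera adjusted p = 0.864, 0.864 and 0.659). Since the covariate hardly differed between the genotypes, it could not move the medians much, and their staying adds nothing against this explanation. The 18S control signals separated the genotypes, and other differences in RNA quality were not tested and stay open. A lower share of hepatocyte RNA cannot be told apart. The mean log2 change of the 46 genes exceeded that of 19 markers of other cells by 0.16 (95% bootstrap interval over genes 0.05 to 0.28), which was the bound set against this explanation. That does not exclude it, because 13 of the 19 markers lay within 1 log2 unit of the dim limit. Against the 6 brighter markers, with a mean of 0.13, the difference was 0.14 with an interval of -0.05 to 0.34. A change in these cells stays open.

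Fatty acid synthesis list higher in the knockout. Time of day at harvest is argued against, since 2 sets of clock genes of opposite phase differed by 0.01 in median log2 change, and the arrays of the genotypes overlapped. Feeding state cannot be told apart: 7 fasting-induced genes had a median log2 change of -0.07, 5 of them lower, with an interval of -0.49 to 0.10. The 18S control signals also separated the genotypes, and what this does to the list was not tested. The genotype stays among the open explanations.

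With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split called 5 genes and the highest other split 0; it was 1 of 10 with as many. At an unadjusted p under 0.05 it gave 1190 genes, and the split of wild-type replicate 1 with knockout replicates 2 and 3 gave 1549. It called 8 lists, and another split called 9, so 2 splits gave as many. The mean log2 change of the fatty acid synthesis list was 0.27 in size, with 0.157 the highest of the others (1 of 10). Near Nrg4, 15 genes had an unadjusted p under 0.01, and 4 was the highest of the others (1 of 10).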

How the results depend on the processing

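The runs with the 5' to 3' covariate and without genes within 20 Mb of Nrg4 were chosen only after the result was seen. Nrg4 kept its direction and passed in every run that tested it. Fatty acid synthesis (medians 0.145 to 0.267), fatty acid oxidation (-0.073 to -0.028) and macrophage markers (0.181 to 0.465) passed camera in 17 of 17 refits. With an estimated correlation none of these 3 passed (camera adjusted p = 0.511, 0.511 and 0.864). With fry, fatty acid synthesis and macrophage markers did not pass (adjusted p = 0.0603 and 0.455). The cause of the changes below was not tested. Genes near the dim limit are measured least well.

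The count of 5 genes became 8 with quantile normalization again, 3 with the 60th percentile filter, 29 with a variance trend, 50 with array weights, 3 with the mean of probe sets, 12 with the 5' to 3' covariate, 30 at adjusted p under 0.10, 2 with treat, and 0 without genes within 20 Mb of Nrg4. Over every probe set 46 probe sets passed, 14 without a gene name here and the others in 30 genes. Leaving out 1 array gave 1 to 17 genes. With a replicate block it was 2; the numbers do not pair the arrays, since same-numbered arrays had deviation correlations of -0.15, 0.03 and -0.01. Near Nrg4, leaving out 1 array gave 0 to 4 genes, and the 60th percentile filter gave 1.

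With an estimated correlation the medians, none past the test, were 0.22 for fatty acid synthesis, -0.039 for fatty acid oxidation and -0.102 for cholesterol (adjusted p = 0.879). With fry, fatty acid synthesis (0.22) and cholesterol (-0.102) did not pass (0.0603 and 0.86).

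Direction turned in 49 list results, 2 of them past the threshold in either fit, and in 5 gene results, none past it. With array weights Egfr was 0.006, Insig1 0.003, and the medians were 0.019 for bile acids, 0.053 for clock genes, 0.006 for ErbB, 0.02 for hepatocytes, 0.001 for pericentral genes and -0.012 for muscle. The 60th percentile filter gave 0.015 for pericentral genes and 0.168 for red blood cells. The mean of probe sets gave -0.048 for Ppara, 0.062 for cell cycle, 0.018 for clock genes and 0.023 for hepatocytes. Centring gave -0.01 for muscle. No filter gave 0.053 for ErbB and -0.043 for neutrophils. Quantile normalization again gave -0.005 for endoplasmic reticulum stress, -0.001 for NRF2 targets and -0.007 for muscle. Without genes within 20 Mb of Nrg4, pericentral genes gave 0.015.

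Leaving out 1 array gave these ranges: cholesterol -0.389 to 0.1, immediate early genes -0.328 to 0.001, ErbB -0.102 to 0.107, acute phase -0.197 to 0.091, bile acids -0.062 to 0.056, cell cycle -0.029 to 0.086, clock genes -0.045 to 0.067, growth hormone axis -0.156 to 0.002, hepatocytes -0.006 to 0.026, male-biased genes -0.162 to 0.03, neutrophils -0.045 to 0.137, NRF2 targets -0.004 to 0.078, pericentral genes -0.04 to 0.079, periportal genes 0 to 0.173, muscle -0.047 to 0.038, Egfr -0.281 to 0.008 and Insig1 -0.276 to 0.069.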

Other observations

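Among genes outside the lists that passed, Cyp2b9, a female-biased cytochrome P450, had the value farthest from 0 in its list, 5.98-fold higher in the knockout (log2 change 2.58, SE 0.66, limma adjusted p = 0.29). The wild-type arrays were 5.85, 4.94 and 2.71, and without the last of these the log2 change was 1.687. Adjusted over the 4 tested genes of the female-biased list alone it passed (limma adjusted p = 0.0151). Over the 15 tested genes of the drug metabolism list alone it did not (limma adjusted p = 0.0517). The gene was chosen after its values were seen. Within lipoprotein assembly, Apoa4 alone passed over all genes, and the list did not pass (camera adjusted p = 0.777).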
